A study of Homo sapiens with 9 samples.

How the data were processed

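RNA of HK1 cells was sequenced in 9 libraries, 3 each from cells given a non-targeting control siRNA, an E2F1 siRNA or an E2F3 siRNA at 100 nM for 48 h. Per the labels' protocols, RNA was extracted with a mirVana kit and libraries were made with standard Illumina protocols. Per the submitters' processing notes, Trimmomatic, TopHat, HISAT2, HTSeq and DESeq were used with genome build GRCh38; their versions, roles and order are not given in the sources used here. The files deposited by the authors hold, per library, FPKM per gene (fragments per kilobase of transcript, scaled to library size and given to 2 decimals, per the file headers). Each file had 59107 gene entries, 58381 with an Ensembl gene identifier and 726 assembled loci without any, and 12 entries of text with no value, which were left out. Of the Ensembl identifiers, 56933 matched GENCODE release 29 exactly and 1328 after the version was dropped, and 120 stayed without a name. Coordinates are those of GENCODE 29 on GRCh38.

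The analysis first planned was a count test. As the files hold FPKM and no counts, neither that test nor the count alternatives planned beside it could be used, and the fallback fixed before the data were examined took its place. Values were taken as log2(FPKM + 1) for genes with at least 1 FPKM in at least 3 of the 9 libraries (13777 genes). All libraries entered a single limma model (limma 3.58.1 in R 4.3.3, with trend and without robust fitting) with a mean per group and no other term, and the 3 comparisons were contrasts of it. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The depth of the libraries relative to each other was read from 2633 single-exon genes of 900 to 1500 bp, whose low values fall on whole steps (93.8 to 97.8% within 0.25 of a whole step). The largest share of identical values between any pair of libraries was 0.532%.

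Before the data were examined, 26 gene lists were fixed: E2F, DP and RB family with MuvB complex; cyclins, their kinases and inhibitors; DNA replication; nucleotide synthesis; homologous recombination and Fanconi anaemia repair; mitosis; histones; p53 targets; apoptosis; interferon response; NF-kB and cytokines; epithelial adhesion; mesenchymal and matrix genes; squamous differentiation; basal keratinocyte genes; cholesterol; hypoxia and glycolysis; unfolded protein and amino acid stress; ribosome biogenesis and MYC; cytosolic ribosomal proteins; nuclear and mitochondrial genes of oxidative phosphorylation (2 lists); small RNA silencing; immediate early genes; markers of other cell types; and reference genes of quantitative PCR. Each was tested with camera from limma, which compares its members with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 26 lists. Named genes followed a rule fixed at the same time: E2F1 to E2F8; per comparison the 5 genes with the largest rise and the 5 with the largest fall among called genes of at least 5 FPKM whose groups do not overlap, without clone names and pseudogenes; the 3 strongest called members of each called list and up to 2 of each other list; and the 5 genes with the smallest adjusted p called in the same and in opposite directions in both knockdowns. LAPTM4B and RPN2, named by the rule for the direct comparison, are also given against control, a choice made after their values were seen, and other genes named for that comparison also fell strongly against control. Some genes that the rule names are not reported here.

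The 3' UTR and coding sequence of 1 transcript per gene (GENCODE 29), that with the longest coding sequence, were searched for all 16384 7-mers. The search was run in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), within 10 strata of length and 3 of GC content. Which transcript the cells made was not determined. The 2010 tested genes without such a UTR were not searched. Random gene sets (100) matched in size, UTR length and GC content to the genes lowest after E2F1 siRNA reached a z of at most 5.19. Other settings tried were scaling by the RLE method or the upper quartile, no filter or a filter of 5 FPKM, only the libraries compared, an added constant of 0.1, a replicate term, adjusted p under 0.01, a log2 change of at least 1, leaving out each library, correction for GC content and length (loess with a span of 0.3), and leaving out genes that hold any of the 3 most over-represented 7-mers. The fits were tested on simulated data for E2F1 siRNA against control (13777 genes, 50 genes changed per fold size, all above 5 FPKM in control). Recovery of lower genes was not tested. The model recovered 44% of genes changed 1.25-fold, 96% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 19 of 188 calls were unchanged genes. A list of 25 genes raised 1.25-fold was called, and 0 of 25 random lists. The simulated genes varied independently of each other, so this cannot show how often lists of genes that move together are called. The 120 nameless entries were tested as genes where they passed the filter. The 726 loci without an identifier had a separate fit of the same form, adjusted over the 641 that passed the filter. No list holds these entries or loci. Figures were drawn with matplotlib 3.10.9.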

Results

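Expression was measured by RNA sequencing in HK1, a cell line from a human nasopharyngeal carcinoma, 48 h after transfection with siRNA at 100 nM. The 9 libraries formed 3 groups of 3: a non-targeting control siRNA, an siRNA against E2F1 and an siRNA against E2F3. E2F1 and E2F3 are transcription factors held in check by the retinoblastoma protein and known for driving genes of S phase entry. Levels were given as FPKM, and 13777 genes with at least 1 FPKM in 3 libraries or more were tested. The absolute depth was not given in the sources used here. Steps in the FPKM of short genes put the depth at 0.846 to 1.211 times that of control replicate 1 in the control libraries, 0.885 to 1.164 times after E2F1 siRNA and 0.98 to 0.997 times after E2F3 siRNA. Mitochondrially encoded genes made up 16.0 ± 0.444% of all FPKM in the control libraries, 14.6 ± 0.640% after E2F1 siRNA and 16.7 ± 0.342% after E2F3 siRNA (SD, n = 3 each). Means below are over 3 libraries, errors of FPKM are SDs, and log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. P-values measure only the spread between these libraries, since the labels do not say whether the 3 libraries of a group came from separate cultures.

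Each siRNA lowered the transcript it was aimed at. E2F1 (20:33675683-33686404 in GRCh38) was at 19.85, 19.53 and 20.2 FPKM in the control libraries, 7.17, 7.95 and 7.33 after E2F1 siRNA, and 21.21, 22.97 and 21.0 after E2F3 siRNA. It fell by 1.30 on the log2 scale after E2F1 siRNA (SE 0.06; limma adjusted p = 3.71e-07), and the change after E2F3 siRNA did not pass the test (log2 0.12; adjusted p = 0.138), though it did after correction for GC content and length (log2 0.23). E2F3 (6:20401906-20493715) was at 24.74, 27.17 and 24.42 FPKM in the control libraries, 29.19, 27.78 and 29.23 after E2F1 siRNA, and 12.61, 10.52 and 11.02 after E2F3 siRNA. It fell by 1.10 after E2F3 siRNA (SE 0.07; limma adjusted p = 3.58e-06), while its value after E2F1 siRNA did not pass the test (log2 0.17; adjusted p = 0.0906). It passed, at log2 0.17, with only the 6 libraries compared and without E2F3 siRNA replicate 1. E2F5, a repressor-type family member, was also lower after both siRNAs, from 31.1 ± 1.77 FPKM to 17.1 ± 1.70 after E2F1 siRNA (log2 -0.83) and 10.5 ± 0.131 after E2F3 siRNA (log2 -1.48). E2F6, which represses without binding the retinoblastoma protein, fell after both (log2 -0.47 and -0.37). E2F8 moved in opposite directions, from 8.22 FPKM to 10.7 after E2F1 siRNA (log2 0.34) and 6.65 after E2F3 siRNA (log2 -0.27), and E2F4 did so from 72.6 FPKM to 84.0 (log2 0.21) and 62.7 (log2 -0.21). The differences of E2F8 and E2F4 between the knockdowns passed the direct test (log2 -0.61 and -0.42; adjusted p = 3.11e-04 and 2.71e-04). The calls against control were less firm: E2F8 after E2F3 siRNA lost its call without any 1 of the control libraries (log2 -0.24 to -0.29) or without E2F3 siRNA replicate 2 (log2 -0.19), and E2F4 lost a call without control replicate 2 (log2 0.16) or E2F1 siRNA replicate 2 (log2 0.19) after E2F1 siRNA and without control replicate 1 (log2 -0.17), control replicate 3 (log2 -0.19), E2F3 siRNA replicate 1 (log2 -0.18) or replicate 3 (log2 -0.19) after E2F3 siRNA. E2F2 was at 11.1 FPKM in control and 13.0 after E2F1 siRNA (log2 0.21, adjusted p = 0.0401), a call lost without any 1 of the 6 libraries compared (log2 0.17 to 0.24). E2F7 did not pass against control after E2F1 siRNA (log2 -0.13) or E2F3 siRNA (log2 -0.17, adjusted p = 0.0734). After E2F3 siRNA it passed with RLE scaling (log2 -0.21), with upper-quartile scaling (-0.18), after correction for GC content and length (-0.24), without E2F1 siRNA replicate 3 (-0.17) and without E2F3 siRNA replicate 1 (-0.22).

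**Figure D1:**
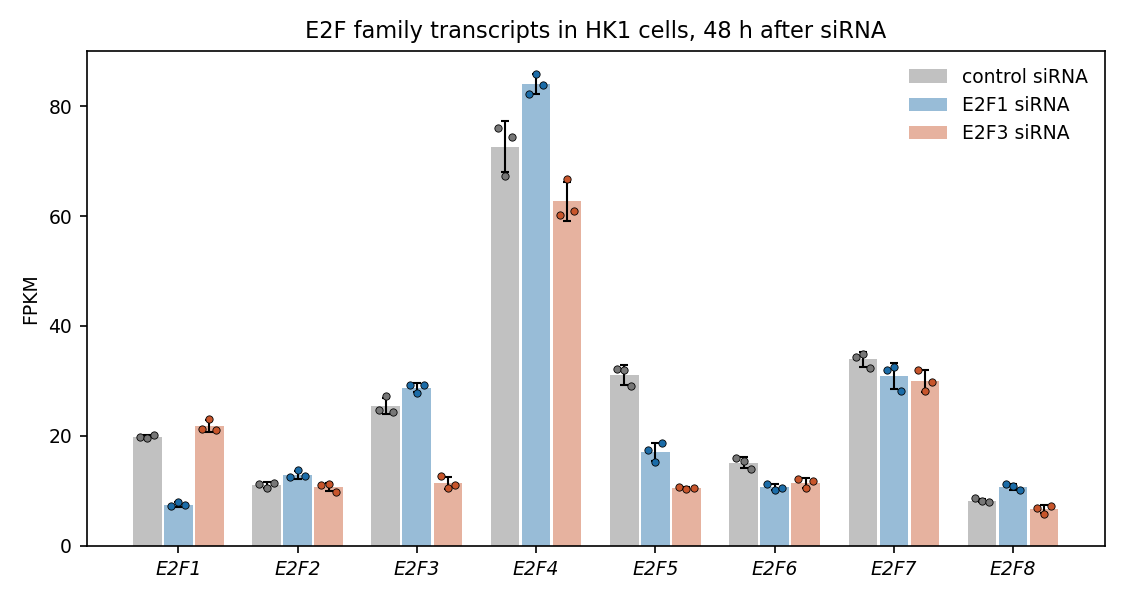
FPKM of the 8 E2F genes in the 9 libraries; bars are group means, error bars SDs and dots the 3 libraries of each group. E2F1 fell to 37.7% of its control mean after its own siRNA, E2F3 to 44.7% after its own, and E2F5 to 54.9% and 33.8% after the E2F1 and E2F3 siRNA.

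After E2F1 siRNA, genes of mitosis were higher than in control. Of the 56 measured members, 43 rose, 1 fell and 12 did not pass the test (45 and 1 adjusted over the list alone). The mitosis median was 0.42 (camera adjusted p = 6.96e-14, and adjusted p = 0.0173 with an estimated correlation). CENPA, the histone variant that marks centromeres, rose from 8.55 to 16.7 FPKM (log2 0.89, SE 0.13); BIRC5 (survivin) and INCENP, partners of Aurora B in the chromosomal passenger complex, rose from 50.2 to 91.5 FPKM (log2 0.85, SE 0.07) and from 34.1 to 61.6 FPKM (log2 0.84, SE 0.05). The DNA replication machinery was also higher: 25 of 50 members rose, 5 fell and 20 did not pass (29 and 5 adjusted over the list alone). The replication median was 0.20 (camera adjusted p = 4.97e-04, and adjusted p = 0.182 with an estimated correlation). TIPIN, of the fork protection complex, rose (log2 0.78), while GINS1, part of the replicative helicase, and POLD3, a subunit of DNA polymerase delta, fell (log2 -0.79 and -0.65). Ribosome biogenesis genes rose in 24 of 35 cases, with 1 lower and 10 not called (26 and 1 adjusted over the list alone). The ribosome biogenesis median was 0.26 (camera adjusted p = 1.25e-07, and adjusted p = 0.0645 with an estimated correlation). NOLC1, a nucleolar phosphoprotein, went from 60.1 to 137 FPKM (log2 1.17, SE 0.04); POLR1B, a subunit of RNA polymerase I, and UBTF, its transcription factor, rose as well (log2 0.70 and 0.64). RBL1, the retinoblastoma relative p107, rose from 14.0 to 26.4 FPKM (log2 0.88, SE 0.08). Its family list did not pass the test (11 of 20 higher, 4 lower, camera adjusted p = 0.247). RBL1, NOLC1, POLR1B and UBTF were also above every control library in every E2F3 siRNA library. RBL1 was at 25.83, 25.01 and 24.07 FPKM there, and NOLC1 at 117.62, 119.24 and 120.73. Genes higher in both knockdowns are weighed further on.

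Mesenchymal and matrix, keratinocyte, cytokine and interferon-stimulated genes were lower after E2F1 siRNA. No measured mesenchymal and matrix gene of 37 rose, 22 fell and 15 did not pass (0 and 24 adjusted over the list alone). The matrix median was -0.31 (camera adjusted p = 1.04e-07, and adjusted p = 0.0645 with an estimated correlation). PLAU, the urokinase plasminogen activator, fell from 28.4 to 6.88 FPKM (log2 -1.90, SE 0.06), fibronectin (FN1) by 0.93 and ACTA2 by 0.95 on the log2 scale. Basal keratinocyte genes were lower in 17 of 26 cases, higher in 2 and not called in 7 (2 and 17 adjusted over the list alone). The basal keratinocyte median was -0.39 (camera adjusted p = 4.69e-07, and adjusted p = 0.0625 with an estimated correlation). The hemidesmosome integrin genes ITGB4 and ITGA6 fell from 124 to 59.5 FPKM (log2 -1.05, SE 0.07) and from 74.8 to 38.9 FPKM (log2 -0.92, SE 0.05), and keratin KRT17 fell from 767 to 400.2 FPKM (log2 -0.94, SE 0.06). Squamous differentiation genes fell in 9 of 18 cases, rose in 1 and were not called in 8 (1 and 10 adjusted over the list alone). The squamous median was -0.49 (camera adjusted p = 6.09e-04, and adjusted p = 0.182 with an estimated correlation). Squamous genes that fell included KRT80 (log2 -0.80), the cornified envelope gene SCEL (-0.90) and filaggrin, FLG (-0.83). The NF-kB and cytokine list had 9 of 21 members lower, 1 higher and 11 not called (1 and 9 adjusted over the list alone). The NF-kB median was -0.21 (camera adjusted p = 0.00659, and adjusted p = 0.218 with an estimated correlation), with interleukin-1 beta (IL1B) falling from 14.1 to 3.27 FPKM (log2 -1.82, SE 0.08), IL6 from 15.4 to 5.41 FPKM (log2 -1.34, SE 0.14) and IL1A by 0.93. Interferon-stimulated genes fell in 19 of 44 cases, rose in 2 and did not pass in 23 (2 and 19 adjusted over the list alone). The interferon median was -0.26 (camera adjusted p = 4.92e-06, and adjusted p = 0.153 with an estimated correlation). DDX60 and STAT2, a helicase and a signal transducer of the interferon response, fell by 1.27 and 1.13, and DTX3L by 0.90.

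Genes of the hypoxia response and glycolysis were lower after E2F1 siRNA as well. In the hypoxia and glycolysis list 21 of 35 members fell, 1 rose and 13 did not pass (1 and 21 adjusted over the list alone). The hypoxia and glycolysis median was -0.21 (camera adjusted p = 4.92e-06, and adjusted p = 0.0645 with an estimated correlation). The glucose transporter SLC2A1 fell from 239.6 to 77.0 FPKM (log2 -1.63, SE 0.07), its relative SLC2A3 by 1.09, and pyruvate kinase PKM from 1294 to 708 FPKM (log2 -0.87, SE 0.03). Cytosolic ribosomal protein genes had 12 of 61 members lower, 1 higher and 48 not called (1 and 6 adjusted over the list alone). The ribosomal protein median was -0.05 (camera adjusted p = 0.00659, and adjusted p = 0.594 with an estimated correlation), a call lost with upper-quartile scaling (adjusted p = 0.0508); RPL14 fell by 0.41, RPL38 by 0.33 and RPLP1 by 0.29. Among single genes, the opioid growth factor receptor OGFR rose from 15.2 to 69.8 FPKM (log2 2.13, SE 0.09), tropomyosin TPM4 from 87.7 to 328 FPKM (log2 1.89, SE 0.04), the helicase DHX37 from 10.5 to 37.2 FPKM (log2 1.74, SE 0.06) and PDXP by 1.65. LAPTM4B, a lysosomal membrane protein, went from 241 FPKM to 22.9 (log2 -3.34). The 4 gene identifiers that share the symbol RNA5-8SN2, copies of the 5.8S ribosomal RNA gene whose reads cannot be told apart, were at 143.93, 41.11 and 183.23 FPKM in the control libraries and listed at 0 in all 6 knockdown libraries, and the small RNA gene RF02195, at 8.33, 60.32 and 23.48 in control, was likewise listed at 0 in those 6.

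By limma, 5210 of the 13777 genes differed between E2F1 siRNA and control, 2830 of them higher and 2380 lower, and 278 of them by at least 1 on the log2 scale (82 higher, 196 lower). Which direction prevailed depended on scaling, as RLE scaling gave 2460 higher and 2659 lower. Groups did not overlap for 6933 genes, against 10% expected by chance for 3 libraries against 3. Of the 26 gene lists, 10 passed camera with its preset correlation, and with an estimated correlation only mitosis did (adjusted p = 0.0173). Splits of the 6 libraries that mixed the groups called up to 9 lists, but at most 1 gene.

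After E2F3 siRNA, interferon-stimulated genes were lower than in control. Of 44 measured members 25 fell, none rose and 19 did not pass the test (1 and 27 adjusted over the list alone). The interferon median was -0.22 (camera adjusted p = 4.20e-10, and adjusted p = 0.0946 with an estimated correlation). OASL, an antiviral oligoadenylate synthetase relative, fell from 110.0 to 20.7 FPKM (log2 -2.36, SE 0.06). IFIT2 and IFIT3 fell from 50.9 to 10.5 FPKM (log2 -2.18, SE 0.08) and from 77.7 to 19.2 FPKM (log2 -1.97, SE 0.08). Squamous differentiation genes fell in 8 of 18 cases, rose in 1 and were not called in 9 (1 and 8 adjusted over the list alone). The squamous median was -0.41 (camera adjusted p = 0.00153, and adjusted p = 0.214 with an estimated correlation). KLK10, a secreted serine protease, went from 3.65 to 0.360 FPKM (log2 -1.77, SE 0.12), the cross-linking enzyme TGM1 from 10.7 to 3.93 FPKM (log2 -1.26, SE 0.15) and the transcription factor KLF4 from 35.6 to 15.4 FPKM (log2 -1.16, SE 0.05). Basal keratinocyte genes were lower in 16 of 26 cases, higher in 5 and not called in 5 (5 and 16 adjusted over the list alone). The basal keratinocyte median was -0.29 (camera adjusted p = 2.28e-04, and adjusted p = 0.0946 with an estimated correlation), with KRT14 falling from 56.3 to 19.8 FPKM (log2 -1.46, SE 0.06), KRT17 by 1.06 and ITGB4 by 0.98. In the NF-kB and cytokine list, which did not pass the test (camera adjusted p = 0.0522), IL6 fell from 15.4 to 2.73 FPKM (log2 -2.12, SE 0.14). That list did pass without control replicate 2 (adjusted p = 0.0335), E2F1 siRNA replicate 1 (0.0481) or replicate 3 (0.0449), E2F3 siRNA replicate 1 (0.0355) or the genes that hold the 7-mers described further on (0.00692).

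The lists of DNA replication, homologous recombination and cyclins were lower after E2F3 siRNA. The DNA replication machinery had 17 of 50 members lower, 7 higher and 26 not called (7 and 18 adjusted over the list alone). The replication median was -0.07 (camera adjusted p = 0.00234, and adjusted p = 0.235 with an estimated correlation). CDC45 and GINS3, parts of the replicative helicase, fell from 37.9 to 19.3 FPKM (log2 -0.94, SE 0.05) and from 18.4 to 9.63 FPKM (log2 -0.87, SE 0.06), and the clamp loader subunit RFC3 fell from 50.8 to 26.8 FPKM (log2 -0.90, SE 0.05). Homologous recombination and Fanconi anaemia genes fell in 13 of 32 cases, rose in 3 and were not called in 16 (3 and 14 adjusted over the list alone). The recombination median was -0.17 (camera adjusted p = 0.00436, and adjusted p = 0.134 with an estimated correlation). Repair genes that fell included the chromatin remodeller HELLS (-0.77) and FANCE (-0.49). Of 28 cyclins, cyclin-dependent kinases and inhibitors, 10 fell, 4 rose and 14 did not pass (6 and 11 adjusted over the list alone). The cyclin median was -0.09 (camera adjusted p = 0.0125, and adjusted p = 0.214 with an estimated correlation). Cyclin D1 (CCND1) fell from 77.7 to 38.4 FPKM (log2 -1.0, SE 0.04), cyclin E2 (CCNE2) from 40.2 to 21.9 FPKM (log2 -0.85, SE 0.05) and the inhibitor p21 (CDKN1A) from 98.0 to 59.1 FPKM (log2 -0.72, SE 0.06). The mitosis list did not pass the test (7 higher, 9 lower and 40 not called of 56; median -0.00177; camera adjusted p = 0.414). Replication-dependent histone genes rose in 8 of 14 cases, fell in none and were not called in 6 (8 and 0 adjusted over the list alone). The histone median was 0.50 (camera adjusted p = 0.00318, and adjusted p = 0.0946 with an estimated correlation). HIST1H2BD rose from 7.94 to 22.6 FPKM (log2 1.41, SE 0.13) and HIST1H2AG from 1.05 to 2.94 FPKM (log2 0.94, SE 0.11). Histone genes are near-identical copies between which reads can be split, so single members are uncertain, and the list lost its call without the genes that hold the 7-mers described further on (adjusted p = 0.0601).

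Genes of the unfolded protein and amino acid stress response and of cholesterol synthesis and uptake were also lower after E2F3 siRNA. In the unfolded protein and amino acid stress list 17 of 34 members fell, 2 rose and 15 did not pass (2 and 17 adjusted over the list alone). The stress median was -0.18 (camera adjusted p = 1.25e-04, and adjusted p = 0.0575 with an estimated correlation). CHAC1, which degrades glutathione, fell from 14.3 to 3.79 FPKM (log2 -1.68, SE 0.12), the stress sensor SESN2 from 13.1 to 4.58 FPKM (log2 -1.34, SE 0.09) and the disulphide isomerase PDIA4 from 135 to 55.2 FPKM (log2 -1.28, SE 0.04). Cholesterol synthesis and uptake genes fell in 9 of 24 cases, rose in 1 and were not called in 14 (3 and 14 adjusted over the list alone). The cholesterol median was -0.17 (camera adjusted p = 5.14e-04, and adjusted p = 0.235 with an estimated correlation); lanosterol synthase (LSS) and SC5D fell by 1.20 and 0.99, and the mevalonate pathway kinase PMVK rose by 0.77. Among single genes, TPM4 rose from 87.7 to 361 FPKM (log2 2.03, SE 0.04), glucosidase II subunit GANAB from 62.0 to 186 FPKM (log2 1.57, SE 0.04), and the zinc finger genes ZNF860 and ZNF629 by 1.66 and 1.55. SMIM11B, a near-identical copy of another gene, was at 15.73, 0.36 and 4.02 FPKM in control and 16.9, 20.57 and 22.64 after E2F3 siRNA (log2 2.11, SE 0.69), and its call was lost without control replicate 2 (log2 1.19), without control replicate 3 (2.13) or without any 1 E2F3 siRNA library (2.02 to 2.22). RPN2, a subunit of the oligosaccharyltransferase, fell by 2.64 on the log2 scale.

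By limma, 5179 genes differed between E2F3 siRNA and control, 2913 higher and 2266 lower, with 283 at a log2 change of at least 1 (114 higher, 169 lower). With RLE scaling the balance turned to 2498 higher and 2595 lower. Groups did not overlap for 6826 genes, against a chance share of 10%. Camera called 9 of the 26 lists, and 0 with an estimated correlation, where the lowest adjusted p was 0.0575, for the unfolded protein list. Mixed splits called up to 11 lists, and at most 2 genes.

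**Figure D2:**
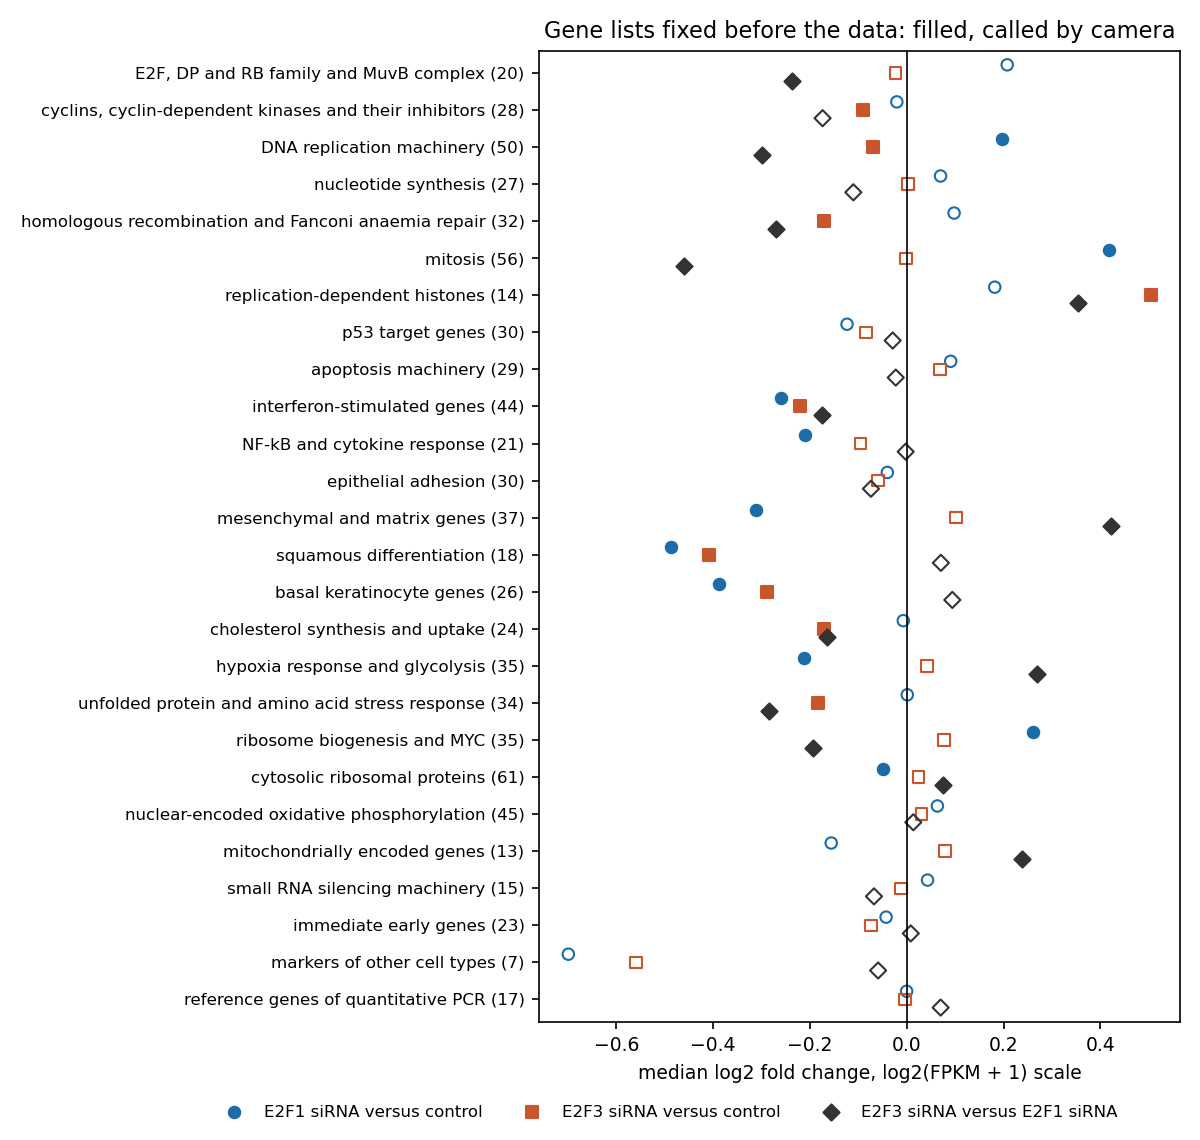
Median log2 fold change of each gene list (number of measured genes in parentheses) in the 3 comparisons; filled symbols passed camera with its preset correlation. Mitosis genes lay at 0.42 after E2F1 siRNA and near 0 (-0.00177) after E2F3 siRNA, with a direct difference of -0.46; medians of the cholesterol, unfolded protein and reference lists after E2F1 siRNA, of the nucleotide, ribosomal protein and oxidative phosphorylation lists after E2F3 siRNA and of the oxidative phosphorylation and immediate early lists in the direct comparison change sign under another scaling.

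The direct comparison set the knockdowns against each other, and the control libraries entered only the choice of genes tested and the estimate of spread. Genes of mitosis, DNA replication and homologous recombination were lower after E2F3 than after E2F1 siRNA. Mitosis genes were 1 higher, 46 lower and 9 not called of 56 (1 and 47 adjusted over the list alone). The mitosis median was -0.46 (camera adjusted p = 4.27e-14, and adjusted p = 0.0166 with an estimated correlation), with the kinesin KIFC1 at 22.4 ± 0.793 FPKM after E2F1 siRNA and 10.7 ± 0.907 after E2F3 siRNA (log2 -1.01), the spindle checkpoint kinase TTK at 43.5 and 22.1 (-0.94) and its partner CDC20 at 128 and 69.0 (-0.88). DNA replication genes were 2 higher, 33 lower and 15 not called of 50 (2 and 34 adjusted over the list alone). The replication median was -0.30 (camera adjusted p = 2.72e-08, and adjusted p = 0.0868 with an estimated correlation). CDC45 stood at 48.4 FPKM after E2F1 siRNA and 19.3 after E2F3 siRNA (log2 -1.28), and POLD1, the catalytic subunit of polymerase delta, and the primase subunit PRIM2 differed by -0.97 and -0.97. Homologous recombination genes were 0 higher, 15 lower and 17 not called of 32 (1 and 15 adjusted over the list alone). The recombination median was -0.27 (camera adjusted p = 0.00500, and adjusted p = 0.116 with an estimated correlation). HELLS (-0.97) and FANCE (-0.83) differed most. Cyclins, their kinases and inhibitors did not pass (6 higher, 14 lower and 8 not called of 28, camera adjusted p = 0.111). The E2F, DP and RB family list was 2 higher, 13 lower and 5 not called of 20 (2 and 13 adjusted over the list alone). The E2F family median was -0.24 (camera adjusted p = 0.00500, and adjusted p = 0.136 with an estimated correlation); LIN52 of the MuvB complex was higher after E2F3 siRNA (log2 0.67). Ribosome biogenesis genes were 2 higher, 21 lower and 12 not called of 35 (2 and 21 adjusted over the list alone). The ribosome biogenesis median was -0.19 (camera adjusted p = 9.14e-05, and adjusted p = 0.116 with an estimated correlation), with RRP12 and TSR1 lower (log2 -1.05 and -0.73) and RRP1B higher (0.63). Histone genes were 7 higher, 0 lower and 7 not called of 14 (7 and 0 adjusted over the list alone). The histone median was 0.35 (camera adjusted p = 0.0408, and adjusted p = 0.141 with an estimated correlation); HIST1H2AC differed by 0.90, and the call was lost without E2F1 siRNA replicate 3 (adjusted p = 0.0678) or E2F3 siRNA replicate 3 (adjusted p = 0.0779), after correction for GC content and length (adjusted p = 0.0564, with the median at 0.33) and without the genes that hold the 7-mers (adjusted p = 0.332).

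Mesenchymal and matrix genes and those of the hypoxia response and glycolysis were higher after E2F3 than after E2F1 siRNA. Mesenchymal and matrix genes were 27 higher, 1 lower and 9 not called of 37 (27 and 1 adjusted over the list alone). The matrix median was 0.42 (camera adjusted p = 7.98e-08, and adjusted p = 0.0868 with an estimated correlation): PLAU stood at 6.88 ± 0.132 FPKM after E2F1 siRNA and 18.9 ± 0.695 after E2F3 siRNA (log2 1.33), type IV collagen COL4A1 at 5.38 and 14.3 (1.27) and integrin ITGAV at 7.53 and 16.8 (1.06). Hypoxia and glycolysis genes were 22 higher, 4 lower and 9 not called of 35 (23 and 4 adjusted over the list alone). The hypoxia and glycolysis median was 0.27 (camera adjusted p = 3.30e-04, and adjusted p = 0.116 with an estimated correlation), with the mitophagy receptor BNIP3L (0.96), ANKRD37 (0.91) and SLC2A1 (0.91) in front. Interferon-stimulated genes were 6 higher, 22 lower and 16 not called of 44 (7 and 22 adjusted over the list alone). The interferon median was -0.17 (camera adjusted p = 0.00500, and adjusted p = 0.329 with an estimated correlation); IFIT2, OASL and IFIT1 differed by -1.81, -1.65 and -1.55. Unfolded protein and amino acid stress genes were 6 higher, 20 lower and 8 not called of 34 (7 and 20 adjusted over the list alone). The stress median was -0.28 (camera adjusted p = 0.00885, and adjusted p = 0.0925 with an estimated correlation), where PDIA4 (-1.31) and CHAC1 (-1.15) were lower and the mTORC1 inhibitor DDIT4 higher (0.94). Cholesterol genes were 4 higher, 12 lower and 8 not called of 24 (4 and 12 adjusted over the list alone). The cholesterol median was -0.16 (camera adjusted p = 0.0113, and adjusted p = 0.402 with an estimated correlation); INSIG1, which holds back sterol synthesis, stood at 128 FPKM after E2F1 siRNA and 31.1 after E2F3 siRNA (log2 -2.01), and the call was lost without the genes that hold the 7-mers (adjusted p = 0.107). Cytosolic ribosomal protein genes were 19 higher, 3 lower and 39 not called of 61 (17 and 2 adjusted over the list alone). The ribosomal protein median was 0.08 (camera adjusted p = 0.0107, and adjusted p = 0.657 with an estimated correlation), a call lost with upper-quartile scaling (adjusted p = 0.0967), after correction for GC content and length (0.0649, with the median at 0.05) and without E2F3 siRNA replicate 3 (0.0636). Mitochondrially encoded genes, whose share of all FPKM was 14.6% after E2F1 siRNA and 16.7% after E2F3 siRNA, were 9 higher, 2 lower and 2 not called of 13 (9 and 2 adjusted over the list alone). The mitochondrial median was 0.24 (camera adjusted p = 0.0184, and adjusted p = 0.544 with an estimated correlation), with MT-CO2 differing by 0.50, a call lost after that correction (adjusted p = 0.601, with the median at 0.03).

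LAPTM4B stood at 22.9 ± 0.635 FPKM after E2F1 siRNA and 219 ± 6.18 after E2F3 siRNA (log2 3.20, SE 0.04; limma adjusted p = 3.98e-11), the carboxypeptidase CPA4 at 10.3 ± 1.11 and 82.7 ± 5.31 (2.90), the galactosyltransferase B4GALT3 at 6.56 ± 0.316 and 39.7 ± 3.95 (2.43) and OSTM1 at 2.16 ± 0.484 and 15.6 ± 1.46 (2.40). In the other direction, RPN2 stood at 219 ± 2.90 FPKM after E2F1 siRNA and 38.8 ± 0.757 after E2F3 siRNA (log2 -2.46, SE 0.03; limma adjusted p = 6.86e-11), mitochondrial transcription factor TFAM at 95.6 ± 1.56 and 18.8 ± 1.57 (-2.29), ERGIC1 of the Golgi intermediate compartment at 63.8 ± 1.44 and 12.9 ± 0.595 (-2.22) and CHCHD10 at 52.3 ± 2.25 and 12 ± 5.17 (-2.13). AATF was at 13.52, 28.19 and 16.07 FPKM after E2F1 siRNA and 1.17, 0.67 and 0.91 after E2F3 siRNA (log2 -3.34, SE 0.75), while the control libraries had 0.7, 0.44 and 14.63. LUZP6, which overlaps another gene so that its reads are uncertain, was listed at 0, 0 and 83.85 FPKM after E2F1 siRNA and at 88.72, 167.82 and 107.77 after E2F3 siRNA, and its call was lost without E2F1 siRNA replicate 1 or replicate 2, any 1 E2F3 siRNA library or control replicate 1 (log2 3.68 to 4.95). In all, 6274 genes differed, 3237 higher and 3037 lower after E2F3 siRNA, 412 of them by at least 1 (237 higher, 175 lower), with groups that did not overlap for 7406 genes against a chance share of 10%. Upper-quartile scaling turned the balance to 2911 higher and 3376 lower. Camera called 13 of the 26 lists, and only mitosis with an estimated correlation. Mixed splits called up to 11 lists, and at most 1 gene.

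Against the shared control, 2028 genes were called in the same direction in both knockdowns, 1285 higher and 743 lower, and 612 in opposite directions. The 9 libraries include no cells without siRNA. A change in the control cells therefore cannot be told from a shared change in both knockdowns. This limit holds for genes lower in both, such as KRT17, ITGB4 and IL6, as well as for genes higher in both. TPM4 rose from 87.7 ± 2.53 FPKM to 328 ± 7.13 after E2F1 siRNA and 361 ± 9.66 after E2F3 siRNA. GANAB (1.61 and 1.57), ZNF664 (1.46 and 1.45), the Golgi matrix gene GOLGA2 (1.24 and 1.17) and the peroxiredoxin PRDX4 (1.40 and 1.48) rose in both on the log2 scale. In opposite directions, SAPCD2 rose from 25.8 FPKM to 43.5 after E2F1 siRNA and fell to 14.8 after E2F3 siRNA, and the galactosyltransferase B4GALT1 (0.56 and -0.83) and PLEKHJ1 (0.58 and -0.68) did the same. The methyltransferase gene CARNMT1 fell from 10.4 FPKM to 3.79 after E2F1 siRNA and rose to 19.4 after E2F3 siRNA, and FAM3C, a secreted factor, followed it (-0.85 and 0.65). Independent calls of these sizes would give 598 genes higher in both, 391 lower in both and 969 in opposite directions. For comparison, all 9 libraries were simulated as unchanged around the control mean of each gene, with 1 simulated control group shared by both comparisons. Across the 13777 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.442, against a simulated 0.501. They had the same sign in 60.9% against 66.7%. Their covariance was 0.0721 against a simulated 0.0106, a difference of 0.0614. The 100 simulations gave at most 0 genes called in the same direction. They held no changed genes and called 0.13 genes on average after E2F1 siRNA. Their overlap was thus near 0 by design and is no chance level for the 2028 genes. The 3 control libraries cannot be split into parts large enough for separate tests.

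**Figure D3:**
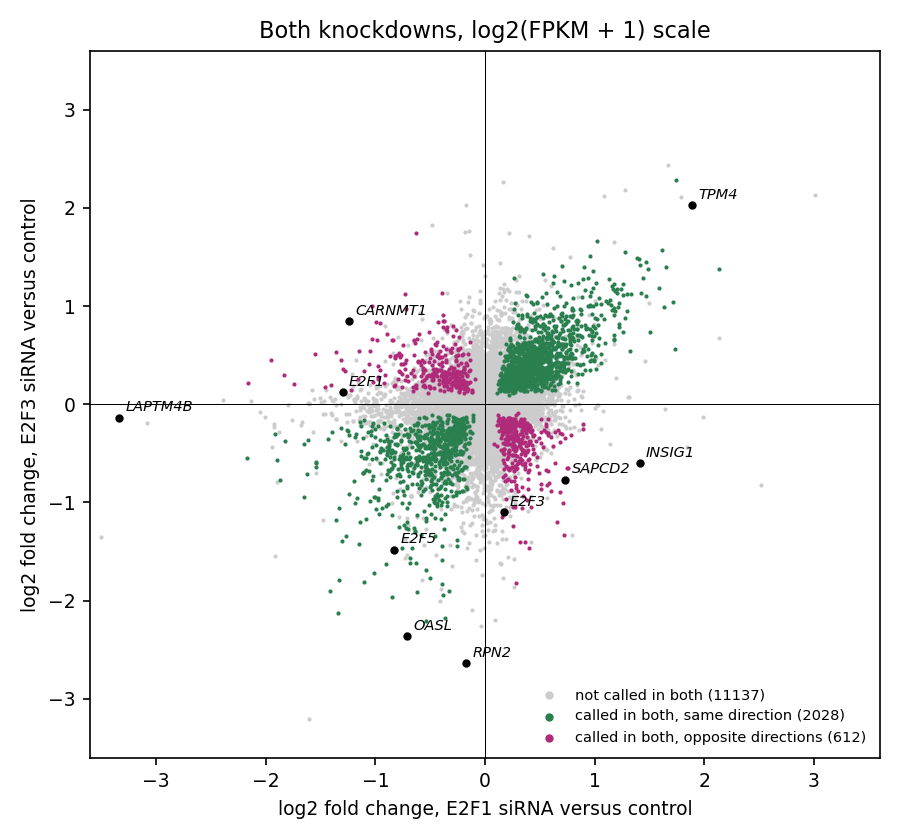
Log2 fold change of each tested gene after E2F3 siRNA against that after E2F1 siRNA, both relative to control; green, called in both in the same direction (2028), magenta, called in opposite directions (612), grey, the others, black, genes named beside their dot, with 7 genes outside the axes of 3.6. TPM4 lies at 1.89 and 2.03, LAPTM4B far to the left and RPN2 near the bottom.

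Genes lower after an siRNA shared short sequences in their 3' untranslated regions (UTRs), searched in 11767 genes. Only 1 transcript per gene was searched, so a site given as present or absent may not hold for other transcripts of that gene. Among 1453 genes lower after E2F1 siRNA than in both other groups, the 7-mer CTCACTG occurred in 587, against 349 expected for UTRs of like length and GC content (adjusted p = 4.68e-68). It occurs in the E2F1 transcript and not in that of E2F3. Among 1430 genes lowest after E2F3 siRNA, TCCAGAT occurred in 293 against 132 expected (adjusted p = 6.72e-58), and it occurs in the E2F3 transcript and not in that of E2F1. Among 1212 genes lowest in the control libraries, GGAGAAA occurred in 346 against 249 expected (adjusted p = 3.49e-12). In the coding sequence of those genes, the overlapping 7-mers CGGAGAA and TCGGAGA occurred in 244 against 137 expected (adjusted p = 1.18e-21) and in 187 against 97.0 expected (adjusted p = 5.89e-21). OGFR holds TCGGAGA 7 times in its coding sequence, and TPM4 holds TCGGAGA and CGGAGAA in its 3' UTR. Of the genes named by rule that fell after E2F1 siRNA, 17 of the 43 searched held CTCACTG in the 3' UTR, and 27 there or in the coding sequence. Holders in the UTR were PLAU, GINS1, POLD3, DTX3L, SLC2A1, SLC2A3, PKM, ITGA6, RPL14, CARNMT1, TYMS, JUP and AGO1 among others, and also COL4A1, ITGAV, BNIP3L, DDIT4, LIN52, CPA4, B4GALT3 and OSTM1. LAPTM4B, IL1B, IL6, IL1A, KRT17 and FAM3C held it in neither region, and FN1 held it in the coding sequence. Of the named genes that fell after E2F3 siRNA, 10 of 49 held TCCAGAT in the 3' UTR, and 19 there or in the coding sequence. Holders in the UTR included RFC3, DICER1, HELLS, KLK10, SESN2, PDIA4, SC5D, B4GALT1 and KIFC1, and also RPN2, ERGIC1 and PRIM2. AATF holds it too, but its control libraries were at 0.7, 0.44 and 14.63 FPKM, so no fall against control can be read. TCCAGAT was absent from the UTRs of OASL, IFIT2, IFIT3, KRT14, CCND1, CDC45 and E2F5, of which CDC45 and E2F5 hold it in the coding sequence. TFAM and CHCHD10, among the largest falls of the direct comparison, held TCCAGAT in neither region. TFAM holds CTCACTG 3 times in its UTR. Yet TFAM was at 96.3, 93.79 and 96.64 FPKM after E2F1 siRNA, against 91.97, 93.42 and 83.28 in control.

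**Figure D4:**
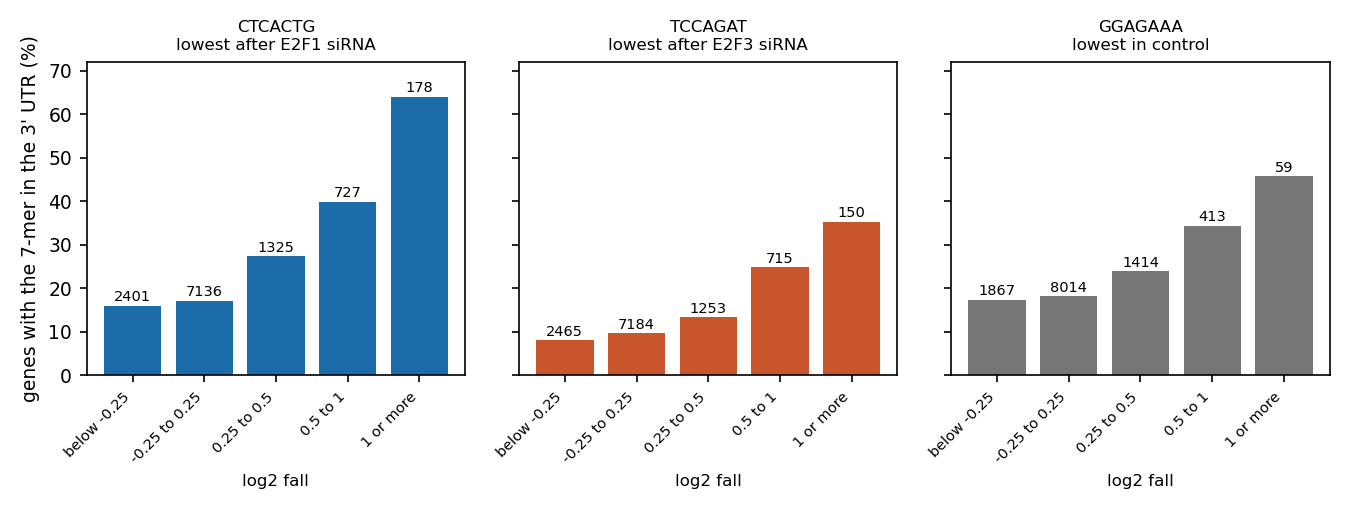
Share of genes whose 3' UTR holds the 7-mer named above each panel, by the log2 fall against control after E2F1 siRNA (left) and E2F3 siRNA (middle), and by how far the control lay below the mean of both knockdowns (right); numbers over the bars count genes. The share with CTCACTG was 17.1% at changes of -0.25 to 0.25 and 64.0% among 178 genes that fell by 1 or more, that with TCCAGAT 9.69% and 35.3%, and that with GGAGAAA 18.2% and 45.8%.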

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

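The gene and list differences here come from tests fixed before the data were examined, and the count of loci without a gene identifier was chosen after the files were seen. Differences between the knockdowns come from the direct test of E2F3 siRNA against E2F1 siRNA.

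The effects of the knockdowns differed by the direct camera test for 13 gene lists, given here as median log2 differences, E2F3 siRNA minus E2F1 siRNA. They were -0.24 for the E2F, DP and RB family, -0.30 for DNA replication, -0.27 for homologous recombination and Fanconi anaemia repair, -0.46 for mitosis, -0.17 for interferon-stimulated genes, -0.16 for cholesterol genes, -0.28 for unfolded protein and amino acid stress genes and -0.19 for ribosome biogenesis. They were 0.35 for histones, 0.42 for mesenchymal and matrix genes, 0.27 for hypoxia and glycolysis, 0.0757 for cytosolic ribosomal proteins and 0.24 for mitochondrially encoded genes. With an estimated correlation only mitosis held (adjusted p = 0.0166). The 3 genes that rose after E2F1 and fell after E2F3 siRNA with the smallest adjusted p differed by -1.50 (SAPCD2), -1.39 (B4GALT1) and -1.26 (PLEKHJ1), and the reverse held for CARNMT1 (2.09) and FAM3C (1.498).

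Of the 726 loci without a gene identifier, 641 were tested, in a fit apart from that of the genes. Of these, 46 were higher and 46 lower after E2F1 siRNA than in control, and 68 were higher and 95 lower after E2F3 siRNA, by limma adjusted p; no sequence or name was read for them.

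Splits of 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The real split gave 5210 genes for E2F1 siRNA, 5179 for E2F3 siRNA and 6274 in the direct comparison, and the highest of the other splits gave 1, 2 and 1. Camera called 10 lists in the real E2F1 split against at most 9 in another, 13 in the direct comparison against at most 11, and 9 in the real E2F3 split against as many as 11 in another. Of the 10 splits, 1 reached the real number of genes in each comparison, the real one, and 1, 2 and 1 reached the real number of lists. Mixed splits called 5 to 9, 0 to 11 and 2 to 11 lists. Their sides are unequal mixtures of the 2 groups, so part of any real difference remains in them. Mixing differing groups also widens the spread within each side. Neither their list counts nor their gene counts therefore show how many calls arise without a difference. For genes called in the same direction in both knockdowns, 1 of 100 regroupings of the 9 libraries, the real one, reached 2028, and the highest other gave 1686. The 8 other regroupings above 100 genes each kept 1 real group whole.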

How the results depend on the processing

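Tests chosen only after the data were seen are the count of DNA replication genes among the lowest genes, the correction for GC content and length, the fit without genes that hold a leading 7-mer, and upper-quartile scaling for the lists. The share of genes with TCGGAGA in either region was also chosen after the data were seen. DESeq2 and limma-voom were not run, since they need counts, and depth beyond the relative steps stays unknown. Counts moved by over 1.5 times at a log2 change of at least 1 (278, 283 and 412 genes for E2F1, E2F3 and the direct comparison), at adjusted p under 0.01 for E2F3 siRNA (3244), and without the 7-mer genes, where fewer genes were tested (3108, 3109, 3852, and 1180 called the same way in both). Lists fell to 1, 0 and 1 with an estimated correlation, and came to 19, 16 and 20 with fry's test of direction and 26, 26 and 26 with its mixed test, which compare no list with other genes. Other settings kept the counts within 1.5 times. Leaving out each library gave 4332 to 5293, 4239 to 5144 and 5423 to 6170 genes, 10 to 11, 9 to 10 and 11 to 13 lists, 1588 to 1875 genes called the same way, and log2 changes of -1.34 to -1.27 for E2F1 and -1.17 to -1.05 for E2F3. Of 4133 alternative values for 261 named results, 4052 kept direction and side of the threshold, 70 lost and 8 gained a call, and 3 reversed, none of them called. Over the fits that left out a library these were ZNF664 in the direct comparison (-0.0374 to 0.0220, reversed without E2F1 siRNA replicate 1), E2F7 there (-0.102 to 0.00394, without E2F3 siRNA replicate 2) and E2F2 after E2F3 siRNA (-0.0781 to 0.00792, without E2F3 siRNA replicate 3). The cause was not tested. Replicate numbers did not pair the libraries: same-number correlations ran from -0.106 to 0.112, with 1 of 9 above 0.1, and others from -0.0768 to 0.0692. With the number as a replicate block, 4936, 4871 and 5982 genes, 10, 9 and 13 lists and 1881 shared genes were called, and the named calls lost were those of E2F2 and LUZP6.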

Other observations

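Some genes moved strongly in lists that camera did not call in the same comparison. Thymidylate synthase (TYMS), which makes the thymidine of DNA, fell from 93.6 ± 5.29 FPKM to 35.8 ± 3.42 after E2F1 siRNA (log2 -1.36), and the serine to glycine enzyme SHMT2 fell after E2F3 siRNA (-0.79); the nucleotide synthesis list had 9 higher and 6 lower and 3 higher and 6 lower of 27. The junction protein JUP (plakoglobin) fell from 162 ± 8.87 FPKM to 58.5 ± 2.87 after E2F1 siRNA (-1.46), and the tight junction gene CLDN4 fell after both siRNAs (-1.31 and -1.39), in an adhesion list with 4 higher and 9 lower and 4 higher and 7 lower of 30. BMF, which promotes apoptosis, rose after E2F3 siRNA (0.72). After E2F1 siRNA it was lower, at 8.84, 9.22 and 6.14 FPKM against 17.1, 15.88 and 14.16 in control. The apoptosis list had 7 higher and 6 lower after E2F1 siRNA and 8 higher and 4 lower after E2F3 siRNA of 29. Among p53 targets BBC3 (PUMA) rose after E2F1 siRNA (0.69) and GDF15 fell after E2F3 siRNA (-0.82), with 6 higher and 8 lower and 5 higher and 9 lower of 30. The cell cycle inhibitor p27 (CDKN1B) fell from 37.5 ± 0.481 FPKM to 16.5 ± 1.63 after E2F1 siRNA (-1.14). TYMS, JUP and BMF hold CTCACTG in the 3' UTR, and CDKN1B and CLDN4 hold neither 7-mer of the knockdowns there. Only the searched transcript of each gene is covered, which for CDKN1B had a 3' UTR of 261 bp.

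The microRNA processing enzyme DROSHA rose from 31.6 ± 1.89 FPKM to 57.3 ± 0.885 after E2F1 siRNA and 54.6 ± 2.96 after E2F3 siRNA (0.84 and 0.77), while DICER1 fell after E2F3 siRNA (-0.76) and AGO1 after E2F1 siRNA (-0.50). DICER1 holds TCCAGAT and AGO1 holds CTCACTG in the 3' UTR. The silencing list had 1 higher and 2 lower and 2 higher and 5 lower of 15. SDHB of succinate dehydrogenase rose after E2F1 siRNA (0.38), and nuclear oxidative phosphorylation genes had 10 higher and 6 lower after E2F1 siRNA and 9 higher and 7 lower after E2F3 siRNA of 45. The immediate early gene IER2 rose after both (0.98 and 0.69), with 4 higher and 8 lower and 5 higher and 3 lower of 23. Of the 7 measured markers of other cell types, the macrophage receptor CSF1R was lower after both (-0.70 and -0.32) and the collagen COL1A1 higher after E2F1 siRNA (0.45). Among 17 reference genes of quantitative PCR, TFRC fell after E2F1 siRNA (-0.74) and GUSB after E2F3 siRNA (-0.70). Camera adjusted p for E2F1 siRNA, E2F3 siRNA and the direct comparison were 0.733, 0.381 and 0.135 for nucleotide synthesis, 0.232, 0.2 and 0.942 for adhesion, 0.677, 0.607 and 0.732 for apoptosis, 0.232, 0.0816 and 0.517 for p53 targets, 0.855, 0.548 and 0.575 for silencing, 0.432, 0.882 and 0.787 for oxidative phosphorylation, 0.526, 0.607 and 0.942 for immediate early genes, 0.360, 0.282 and 0.942 for other cell types and 0.232, 0.882 and 0.472 for reference genes. Without the genes that hold the 7-mers, p53 targets (adjusted p = 0.0370) and adhesion (adjusted p = 0.0430) passed after E2F3 siRNA, and mitochondrially encoded genes passed after E2F1 siRNA (adjusted p = 0.0436), as they did without E2F1 siRNA replicate 1 (adjusted p = 0.0332).

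For the weighing that follows, the search for 7-mers was planned before its result was seen, and the tests of GC content and length and of the DNA replication genes were chosen after the sets of genes were seen. All explanations are hypotheses tested on the data in which the sets were found, and the siRNA sequences are not given in the sources used here.

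Genes lowest after E2F1 siRNA: CTCACTG in their 3' UTRs had a z of 17.9, against at most 5.19 in random sets, and it occurs in the E2F1 transcript, which a seed of the E2F1 siRNA would need. The data are consistent with silencing of unintended transcripts through that seed for part of the set, since 587 genes held it against 349 expected and 40.4% of the set at all. A trend over GC content or transcript length is argued against as the whole cause, as 92.3% of the genes kept both calls after correction. The set held 2 of the 50 DNA replication genes against 6.17 expected. This argues against loss of activation of that list as a whole by E2F1, for these 50 genes only. So short a list cannot show what the source of the whole set was. That list had already been seen higher after E2F1 siRNA, so the count restates it. Other targets of E2F1 were not tested. What moved the genes without a site stays open.

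Genes lowest after E2F3 siRNA: TCCAGAT had a z of 16.6 and occurs in the E2F3 transcript, which is consistent with silencing through the seed of the E2F3 siRNA for part of the set (20.5% of the genes held it against 9.20% expected). GC content or length is argued against as the whole cause, since 90.5% kept both calls after correction. The set held 16 of the 50 DNA replication genes against 6.08 expected, 3 of them with TCCAGAT in the UTR. Since that list had already been seen lower, this count restates it, and loss of activation of these genes by E2F3 stays open.

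Genes lowest in the control libraries, which appear as higher in both knockdowns: GGAGAAA had a z of 8.13. Random sets, matched to the set lowest after E2F1 siRNA and not to this one, reached at most 5.19. Genes highest in a group reached 6.48 in their UTRs. That value belonged to CCAGATA in genes highest in control, and CCAGATA overlaps TCCAGAT, so it is no chance level. Coding sequences gave other, overlapping 7-mers, CGGAGAA (z 10.5) and TCGGAGA (z 10.2), where genes highest in a group reached 8.64. TCGGAGA, picked for this count after the search was seen, lay in either region in 19.3% of the set and 8.48% of genes outside it. Among the 59 genes at least 1 lower in log2 in control than the mean of both knockdowns, 24 (40.7%) held it. Those shares were not matched for length or GC content. These 7-mers also occur in a target transcript, GGAGAAA in that of E2F3 and the others in that of E2F1, so such an occurrence is by itself weak evidence for a seed. Silencing through the seed of the control siRNA is a candidate explanation for part of the 1212 genes, of which 28.5% held GGAGAAA against 20.5% expected, and GC content or length is argued against as the whole cause, as 87.9% kept both calls after correction. The rise of GANAB (GGAGAAA in the UTR) and TPM4 (TCGGAGA and CGGAGAA there) may thus not be an effect of either knockdown, but ZNF664, which rose in both, holds none of these 7-mers, and no biological explanation was tested.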
